A study of Mus musculus with 147 samples.

How the data were processed

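RNA was measured in macrophages and monocytes of mice in 147 libraries from 2 experiments. In the refeeding experiment, 110 libraries of 7 populations came from mice fasted for 12 h or fasted for 12 h and then fed again for 2 h, in 4 cohorts. In the diet experiment, 37 libraries of islet macrophages, peritoneal macrophages and microglia came from mice on normal diet, on high-fat diet for 8 weeks, or on high-fat diet for 8 weeks with streptozotocin (STZ, a toxin of insulin-producing beta cells) at week 4, in 8 cohorts. Per the labels, cells were sorted by flow cytometry, RNA was extracted with a PicoPure kit and polyA libraries were made by Smart-seq2. A library started from 400 cells in the refeeding experiment and in the islet libraries of the diet experiment, from 100000 cells in its peritoneal libraries and from 5000 cells in its microglia libraries.

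The deposited values are raw read counts per gene for each library. Per the labels, the authors trimmed reads with Trimmomatic 0.36, aligned them to mm10 with STAR 2.5.1a and counted them with featureCounts. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The tables held 50686 versioned Ensembl identifiers, of which 50376 matched a symbol of the GENCODE M21 annotation of the same assembly without the version and 45737 with it. Identifiers without a symbol held 0.0438% of all counts. Gene positions are from that annotation, which may not be the release used for counting. Because the strand setting is unknown, reads of a gene whose exons overlap another gene may belong to either, which applies to 53 of the 205 genes looked up.

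Depth ran from 7.92 to 27.3 M counts per library in the refeeding experiment and from 11.4 to 34.5 M counts in the diet experiment. Smart-seq2 reads carry no molecular identifiers, so counting error understates the error of a library made from few cells, and the spread between libraries was used for every test. Among 443 pairs of libraries of the same group, 0 held identical counts.

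Libraries were grouped by population and treatment as labelled. Descriptions of 4 refed libraries (islet replicates 1_2 and 3, Kupffer replicates 1 and 2) name fasting only, while their titles and treatment fields say refed. They were kept as refed and left out in an alternative. There 23 of 23 results for named genes were the same by sign and call, but edgeR called 0 genes in these populations with all libraries. No list was tested in that alternative. Islet replicates 1_2 and 5_6 carry the numbers of 2 mice. In the refeeding experiment same-numbered fasted and refed libraries share a number and a cohort but no animal, and the cohort entered each fit as a term. In islet and peritoneal libraries of the diet experiment the replicate number is the cohort, so it entered the fit as a block. Within-group residuals of same-numbered libraries of that experiment had a mean correlation across genes of 0.078 in 10 islet pairs, 2 of them above 0.1, and of 0.164 in 13 peritoneal pairs, 9 of them above 0.1.

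Each of 16 comparisons was fitted within a population with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and the quasi-likelihood F test was run with robust dispersions. P values were adjusted by Benjamini-Hochberg over the tested genes and called below 0.05. Without any change, a share of about 0.05 of the tested genes is expected at an unadjusted p below 0.05. A share at or below that shows no excess of small p. Levels are CPM on the scaled library sizes, given as mean ± SD over libraries. A log2 fold change is that of the fit, and its standard error (SE) is its size divided by the square root of F. Joint fits with population and cohort tested whether a refeeding, diet or STZ effect differed among populations, and fasted libraries were compared between all pairs of populations. These fits used a single spread per gene for all populations. A gene was specific to a population when all 6 differences were at least 1 on the log2 scale and each passed the adjusted p.

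Before the data were examined, 60 gene lists were written from general knowledge (34 of responses, 8 of population markers and 18 of other cells that a sort could carry), together with the fits, the alternatives and the naming rule. Lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, which compares a list with the other genes, and adjusted by Benjamini-Hochberg over the lists of a comparison. An estimated correlation was the alternative. With it 1 of 134 list calls was kept, so each other list result rests on the preset value. Members past 0.05 were counted over all genes and adjusted over the list alone. Other-cell levels are the summed CPM of a list without scaling.

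Named genes followed the rule. In each comparison they were, among genes with an adjusted p below 0.05, an average log2 CPM of at least 4, a proper symbol and the same sign in every cohort, up to 8 with the highest and up to 8 with the lowest fold change. Up to 4 members of each called list with the smallest p were added, and the 3 genes with the smallest p where fewer than 3 passed. Joint fits gave their 8 smallest p, and the comparison of populations gave 5 genes per population. Of these, the genes printed were picked after their values were seen, and some results of that rule are not reported here, nor counted among the sets searched for a library that stands apart.

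Alternatives set before the data were examined were DESeq2-type size factors in edgeR (RLE), no low-count filter, DESeq2 1.42.0, limma voom with quality weights, no cohort term or another block, the animal as a random block, leaving out each library of the diet experiment, and leaving out the 4 libraries above. Alternatives chosen after seeing the data were leaving out libraries with a voom quality weight below 0.5, which in peritoneal macrophages of the diet experiment are both libraries of cohort 3, DESeq2 on genes counted in at least 0.5 of the libraries, leaving out 4 colonic libraries rich in pancreatic or epithelial RNA, and leaving out 2 microglia libraries with neutrophil or B-cell RNA. Group labels were also permuted: exact tests over animals and libraries kept the cohorts, and counts of called genes were compared with other splits of the libraries.

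The fits were tested on simulated data after the first fits of the real data. Known fold changes were put into counts simulated with the depth and spread of each comparison, which were then fitted with its design. The simulated counts held no cohort effect and no correlation between genes, so the shares called in real data may differ. A 4-fold change was called for 62.9% of the changed genes in the refeeding comparison of peritoneal macrophages. The share was 35.5% in adipose tissue macrophages, 28.6% in microglia, 10.9% in islet macrophages, 22.6% in Kupffer cells, 28.3% in colonic macrophages and 50.8% in monocytes. For high-fat diet with STZ against normal diet it was 78.5% in peritoneal macrophages, 13.6% in islet macrophages and 32.8% in microglia.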

Results

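Transcript counts were available for 7 mouse populations after 12 h of fasting or after fasting and 2 h of refeeding, and for 3 of these populations on normal diet, high-fat diet or high-fat diet with STZ. The refeeding groups held 8 fasted and 9 refed libraries of adipose tissue macrophages, microglia, colonic macrophages and blood monocytes, 6 fasted and 7 refed libraries of islet macrophages and Kupffer cells, and 8 of each of peritoneal macrophages. The diet groups (normal, high-fat, high-fat with STZ) held 4, 4 and 3 islet, 5, 4 and 5 peritoneal and 4, 4 and 4 microglia libraries. Depth per library ran from 7.92 to 27.3 M counts in the refeeding experiment and from 11.4 to 34.5 M counts in the diet experiment. Levels are CPM as mean ± SD over libraries, fold changes are log2 values with their SE from edgeR, and positions are mm10 coordinates of the GENCODE M21 annotation.

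In fasted mice, 670 of 16114 genes were specific to 1 of the 7 populations by edgeR, from 35 in adipose tissue macrophages to 169 in microglia. Sall1, a transcription factor that maintains microglial identity, stood at 477 ± 108.1 CPM in microglia (n = 8) and was at least 10.92 log2 units above each other population (largest adjusted p 6.98e-10). Clec4f, a lectin of Kupffer cells, reached 9361 ± 2155 CPM in them (n = 6, smallest log2 difference 11.42). Prg4, which encodes lubricin, reached 13779 ± 1029.5 CPM in peritoneal macrophages (n = 8, 10.19), and Ly6c2, a surface marker of classical monocytes, 1502 ± 373 CPM in monocytes (n = 8, 6.76). Transcripts of neighbouring cells were among the specific genes too. Islet macrophages carried Ins2 (1134 ± 644 CPM) and Ins1 (441 ± 249 CPM), which encode insulin and are near-identical in part, so reads may be shared between them. Adipose tissue macrophages carried the adipocyte genes Cfd (53.3 ± 21.5 CPM) and Cidec (41.9 ± 21.4 CPM), Kupffer cells the hepatocyte gene Fga (65.7 ± 33.3 CPM), and colonic macrophages the plasma-cell genes Igha (13462.5 ± 17177 CPM) and Jchain (2819 ± 3752 CPM). On the marker list of its own population, each library of 6 populations scored above all libraries of the other populations. For islet macrophages 1 of 24 libraries did, so the islet list written here does not separate that population.

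Refeeding raised chaperone genes in peritoneal macrophages. Hsph1, a co-chaperone of the HSP70 family (chromosome 5, 149614287 to 149636376, minus strand), rose by 2.46 ± 0.40 log2 units, from 17.3 ± 13.6 CPM in 8 fasted to 78.3 ± 44.6 CPM in 8 refed libraries (adjusted p 0.0158). Hspa8, the constitutive HSP70 (chromosome 9, 40800984 to 40810087), rose from 858 ± 82.6 to 1782 ± 851 CPM (log2 1.02 ± 0.19, adjusted p 0.0235), and its exons overlap 3 small nucleolar RNA genes on the same strand. The glucose transporter gene Slc2a1 (chromosome 4, 119108711 to 119137983) rose from 8.64 ± 3.66 to 33.8 ± 15.3 CPM (1.89 ± 0.32, adjusted p 0.0186), and the exons of Gm12868 overlap it on the other strand. Mertk, a receptor for the uptake of dying cells (chromosome 2, 128698956 to 128802894), fell from 181 ± 28.8 to 94.4 ± 33.6 CPM (adjusted p 0.00978). Stxbp3, a regulator of vesicle fusion at which GLUT4 is delivered, fell from 198 ± 44.6 to 87.02 ± 33.1 CPM (-1.23 ± 0.15, adjusted p 0.00325).

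In all, edgeR called 49 of 11331 genes in this comparison, 37 higher and 12 lower in refed mice. Other genes that rose were the cell-cycle regulator Rgcc (2.29 ± 0.47), the microtubule-binding gene Tppp3 (2.19 ± 0.41), the differentiation inhibitor Id1 (1.97 ± 0.36), the nuclear lamin gene Lmna (1.65 ± 0.30) and the cytokine-signalling inhibitor Socs3 (1.14 ± 0.20), with adjusted p from 0.0235 to 0.0403. Genes that fell included Pdk3, a kinase gene whose product inhibits pyruvate dehydrogenase (-1.18 ± 0.22, adjusted p 0.0235), and the adaptor gene Gab2 (-1.02 ± 0.19, adjusted p 0.0235). The immediate early gene Egr1 fell too (-0.96 ± 0.20, adjusted p 0.0493). Of 18 tested heat shock genes 17 were higher in refed mice, with a median log2 change of 0.73. As a set they rose (camera adjusted p 4.14e-17, adjusted p = 0.108 with an estimated correlation), with 2 called over all genes and 14 adjusted over the list alone. The unfolded protein response genes, which refold proteins of the endoplasmic reticulum, rose too (median 0.36, 23 of 25 higher, camera adjusted p 1.01e-12, adjusted p = 0.191 with an estimated correlation). Within that list Herpud1 went from 153 ± 12.6 to 257 ± 60.5 CPM (adjusted p 0.00978) and Creld2 from 73.5 ± 19.9 to 185 ± 72.4 CPM (adjusted p 0.0303). Glycolysis genes rose (median 0.26, 16 of 19 higher, camera adjusted p 4.97e-05, adjusted p = 0.108 with an estimated correlation). Genes of ribosome biogenesis and MYC targets moved likewise (median 0.34, 28 of 34 higher, camera adjusted p 1.11e-05, adjusted p = 0.284 with an estimated correlation). Genes of cytosolic ribosomal proteins fell (median -0.19, 0 of 61 higher, camera adjusted p 3.59e-13, adjusted p = 0.332 with an estimated correlation). Fatty acid oxidation and PPAR target genes also fell (median -0.31, 8 of 27 higher, camera adjusted p 0.000523, adjusted p = 0.108 with an estimated correlation). Mitochondrial genes took 2.00 to 3.14% of the counts of fasted and 1.37 to 2.10% of those of refed libraries, and as a set they fell (median -0.22, 0 of 7 higher, camera adjusted p 0.0153, adjusted p = 0.371 with an estimated correlation). Dendritic cell genes rose (median 0.63, 6 of 7 higher, camera adjusted p 0.0482, adjusted p = 0.332 with an estimated correlation), with no call by voom or with the replicate number as the block. The lipid droplet gene Plin2 stood at 996 ± 63.6 CPM fasted and 667 ± 215 CPM refed (adjusted p 0.0845). With the replicate number as the block in place of the cohort, edgeR called 0 genes, where voom with quality weights called 191 and DESeq2 598 with the cohort term and 1245 genes had an unadjusted p below 0.05.

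**Figure D1:**
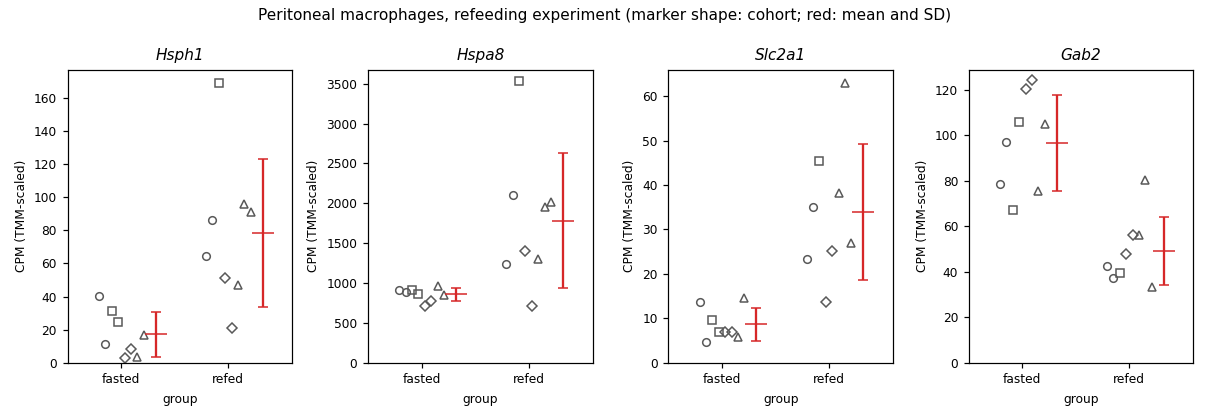
Level (CPM) of Hsph1, Hspa8, Slc2a1 and Gab2 in each of 8 fasted and 8 refed libraries of peritoneal macrophages. Marker shape gives the cohort and red marks the mean with SD. Hsph1 averaged 17.3 CPM in fasted and 78.3 CPM in refed mice, and Gab2 averaged 96.7 and 49.2 CPM.

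Adipose tissue macrophages of refed mice expressed more inflammatory genes as a set. The monocyte-attracting chemokine genes Ccl7 (168 ± 105.1 CPM in 8 fasted, 1051 ± 846 CPM in 9 refed libraries, log2 2.53 ± 0.54) and Ccl2 (607 ± 320.0 and 1810.3 ± 949 CPM, 1.62 ± 0.38) did not pass singly, with adjusted p of 0.213 and 0.297. The NF-kB inflammatory genes rose as a set (median 0.60, 27 of 30 higher, camera adjusted p 1.42e-15, adjusted p = 0.0797 with an estimated correlation). Of its members 0 were called over all genes by edgeR and 11 adjusted over the list alone. RNA of mesothelium and fibroblasts, cells that express Ccl2 and Ccl7 too, rose in the same comparison, from 133 ± 172 to 334 ± 305 CPM summed over that list (median 3.79 over 5 genes, camera adjusted p 0.000124, adjusted p = 0.147 with an estimated correlation). Without fasted replicate 5 and refed replicate 6, of low voom weight, that median was 5.64. Which cells the inflammatory RNA came from was not tested. The immediate early genes rose as well (median 0.33, 21 of 28 higher, camera adjusted p 0.000222, adjusted p = 0.147 with an estimated correlation), but members went both ways. Egr2, an activation-induced transcription factor, stood at 226 ± 107.4 CPM fasted and 884 ± 535 CPM refed (1.95 ± 0.41, adjusted p 0.201), while Jun stood at 3503 ± 608 and 2224 ± 511 CPM (-0.64 ± 0.14, adjusted p 0.236).

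Hspa1a, the inducible HSP70 gene, had the smallest p in these cells and pointed downward (532 ± 202 CPM fasted, 205 ± 56.6 CPM refed, -1.29 ± 0.20, adjusted p 0.0869). It shares nearly all of its sequence with Hspa1b, so reads may be split between them. Fatty acid oxidation and PPAR target genes fell as a set (median -0.18, 12 of 29 higher, camera adjusted p 0.0187, adjusted p = 0.197 with an estimated correlation). Without fasted replicate 5 and refed replicate 6 their median was -0.07, and the call was not made with the replicate number as the block. Among them Angptl4, an inhibitor of lipoprotein lipase, stood at 262 ± 39.6 CPM fasted and 93.9 ± 108.9 CPM refed (adjusted p 0.555), and Cpt1a, which carries fatty acids into mitochondria, at 283 ± 40.005 and 187 ± 76.8 CPM (adjusted p 0.744). Cell cycle genes fell (median -0.42, 8 of 35 higher, camera adjusted p 0.00298, adjusted p = 0.236 with an estimated correlation). Over all 10924 genes edgeR called 0, with 564 (5.16%) at an unadjusted p below 0.05. There were 5 called by voom with quality weights, 738 by DESeq2 and 124 by DESeq2 on genes counted in at least 0.5 of the libraries.

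Kupffer cells shared the rise of the unfolded protein response. Its genes rose as a set (median 0.46, 21 of 25 higher, camera adjusted p 3.84e-14, adjusted p = 0.0621 with an estimated correlation), with 13 called adjusted over the list alone and 0 over all genes by edgeR. The folding factors Sdf2l1 (63.0 ± 20.97 CPM in 6 fasted, 153 ± 51.5 CPM in 7 refed libraries, 1.28 ± 0.27) and Creld2 (48.6 ± 23.2 and 140.0 ± 63.2 CPM, 1.56 ± 0.35) each had an adjusted p of 0.788. The chaperone gene Hsp90ab1 stood at 974 ± 117.4 CPM fasted and 1554 ± 305 CPM refed (0.69 ± 0.14, adjusted p 0.788), within a heat shock list that rose (median 0.12, 12 of 19 higher, camera adjusted p 0.00174, adjusted p = 0.35 with an estimated correlation). Without refed replicate 8, of low voom weight, that median was 0.21. Fatty acid oxidation and PPAR target genes fell (median -0.43, 5 of 30 higher, camera adjusted p 0.00011, adjusted p = 0.0621 with an estimated correlation). Plin2 stood at 665 ± 99.6 CPM fasted and 421 ± 112.3 CPM refed (adjusted p 0.993) and Angptl4 at 66.8 ± 46.6 and 6.99 ± 6.30 CPM (adjusted p 1).

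Selenop, a secreted selenium carrier, stood at 4206 ± 787 CPM fasted and 2809 ± 483 CPM refed in Kupffer cells (-0.60 ± 0.12, adjusted p 0.788), and its exons overlap Ccdc152 on the other strand. Glucocorticoid receptor target genes fell as a set (median -0.33, 5 of 24 higher, camera adjusted p 0.00218, adjusted p = 0.323 with an estimated correlation). Markers of liver endothelial and stellate cells moved with them, from 4585 ± 1558 to 3026 ± 2008 CPM (median -0.80, 2 of 12 higher, camera adjusted p 0.00011, adjusted p = 0.367 with an estimated correlation). Genes of endothelial cells in general and of erythrocytes fell too (medians -0.71 and -2.26, camera adjusted p 0.00011 and 0.0471, adjusted p = 0.35 each with an estimated correlation), the erythrocyte call being lost without refed replicate 8 (0.0686) and with the replicate number as the block. Clec4g, a lectin gene of liver sinusoids, stood at 643 ± 184 and 402 ± 283 CPM (adjusted p 1). Ccn2, which encodes a matrix signalling protein, was at 21.3 ± 18.9 CPM in fasted libraries and had 0 counts in refed ones (adjusted p 0.788). Of 11635 genes edgeR called 0, with 380 (3.27%) at an unadjusted p below 0.05. There were 16 by voom with quality weights and 369 by DESeq2. No list of these cells was tested without refed replicates 1 and 2, whose descriptions name fasting only.

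In islet macrophages, refeeding lowered genes of fatty acid oxidation. That list was the only one of 134 list calls kept with an estimated correlation (median -0.55, 5 of 26 higher, camera adjusted p 3e-07, adjusted p = 0.04 with an estimated correlation), and 3 genes were called lower adjusted over the list alone. Cpt1a stood at 191 ± 43.9 CPM in 6 fasted and 59.7 ± 25.1 CPM in 7 refed libraries (-1.70 ± 0.33, adjusted p 1), Plin2 at 1037 ± 213 and 696 ± 251 CPM (-0.63 ± 0.16, adjusted p 1) and Acaa2, a thiolase of beta oxidation, at 70.8 ± 35.4 and 24.8 ± 12.1 CPM (-1.45 ± 0.48, adjusted p 1). Aldh9a1, which makes a carnitine precursor (chromosome 1, 167349991 to 167368532), had the smallest p, at 224 ± 20.6 CPM fasted and 116.3 ± 17.2 CPM refed (-0.95 ± 0.16). Heat shock genes rose as a set (median 0.24, 17 of 19 higher, camera adjusted p 0.000484, adjusted p = 0.878 with an estimated correlation), and genes encoded by mitochondrial DNA fell (median -0.31, 0 of 7 higher, camera adjusted p 0.00537, adjusted p = 0.878 with an estimated correlation). Pancreatic acinar RNA stood at 722 ± 292 CPM fasted and 536 ± 413 CPM refed, and its list fell (3 of 16 higher, camera adjusted p 0.0388, adjusted p = 0.878 with an estimated correlation). That call was lost without refed replicate 9, of low voom weight (median -0.43, adjusted p 0.156), by voom and with the replicate number as the block. Over 10059 genes edgeR called 0, with 243 (2.42%) at an unadjusted p below 0.05. There were 0 by voom with quality weights and 513 by DESeq2. No list of these cells was tested without refed replicates 1_2 and 3, whose descriptions name fasting only.

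Microglia of refed mice expressed more heat shock genes as a set (median 0.54, 13 of 19 higher, camera adjusted p 3.45e-06, adjusted p = 0.545 with an estimated correlation), with 5 called adjusted over the list alone. Hspa1a stood at 82.3 ± 87.1 CPM in 8 fasted and 317 ± 415 CPM in 9 refed libraries (2.96 ± 0.82, adjusted p 1), and Hspa8 at 742 ± 417 and 1146 ± 670.3 CPM (0.81 ± 0.23, adjusted p 1). Cirbp, an RNA-binding protein induced by cold (chromosome 10, 80165985 to 80172786), had the smallest p and stood at 187 ± 55.6 CPM fasted and 66.1 ± 53.9 CPM refed (-1.64 ± 0.34, adjusted p 0.77). The unfolded protein response genes rose (median 0.16, 21 of 25 higher, camera adjusted p 0.0051, adjusted p = 0.635 with an estimated correlation). Without refed replicates 5 and 6, which held RNA of neutrophils or B cells, their median was 0.25. Of 10438 genes edgeR called 0, with 270 (2.59%) at an unadjusted p below 0.05. There were 0 by voom with quality weights, 1491 by DESeq2 and 60 by DESeq2 on genes counted in at least 0.5 of the libraries.

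Colonic macrophages showed the same direction for the unfolded protein response (median 0.29, 23 of 25 higher, camera adjusted p 2.08e-07, adjusted p = 0.523 with an estimated correlation). Manf, a secreted factor of endoplasmic reticulum stress, stood at 100.99 ± 18.9 CPM in 8 fasted and 151 ± 33.8 CPM in 9 refed libraries (0.58 ± 0.17, adjusted p 1), with exons that overlap 3 other genes. Cell cycle genes fell as a set (median -1.37, 7 of 37 higher, camera adjusted p 1.94e-07, adjusted p = 0.834 with an estimated correlation), and interferon-stimulated genes rose (median 0.23, 31 of 40 higher, camera adjusted p 0.00653, adjusted p = 0.897 with an estimated correlation). Pancreatic enzyme RNA was abundant in these libraries. Summed over the acinar list it had a median of 20582 CPM in fasted libraries (maximum 257367) and of 16822 CPM in refed libraries (maximum 35805). The acinar list fell as a set (median -1.93, 0 of 19 higher, camera adjusted p 2.76e-09, adjusted p = 0.834 with an estimated correlation), while the lipase gene Cel spread over 8317 ± 13662 CPM in fasted and 781 ± 697 CPM in refed libraries (adjusted p 1). Without 4 libraries rich in pancreatic or epithelial RNA (fasted replicates 3 and 5, refed replicates 7 and 8) the acinar median was -0.44 with an adjusted p of 0.00556. The cell cycle median was then -0.73 (adjusted p 5.96e-06) and the interferon median 0.37, and the interferon call was not made by voom with all libraries. T cell and NK cell genes fell with all libraries (camera adjusted p 0.0304 and 0.0374, each 0.834 with an estimated correlation) and did not pass without the 4 (0.336 and 0.437). Plasma-cell RNA had a median of 11589 CPM in fasted and 37078 CPM in refed libraries, and Igkv1-135, an antibody light chain gene, stood at 1.90 ± 4.14 and 575 ± 904 CPM (adjusted p 0.857). Of 11856 genes edgeR called 0, with 307 (2.59%) at an unadjusted p below 0.05. There were 5 by voom with quality weights and 400 by DESeq2.

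**Figure D2:**
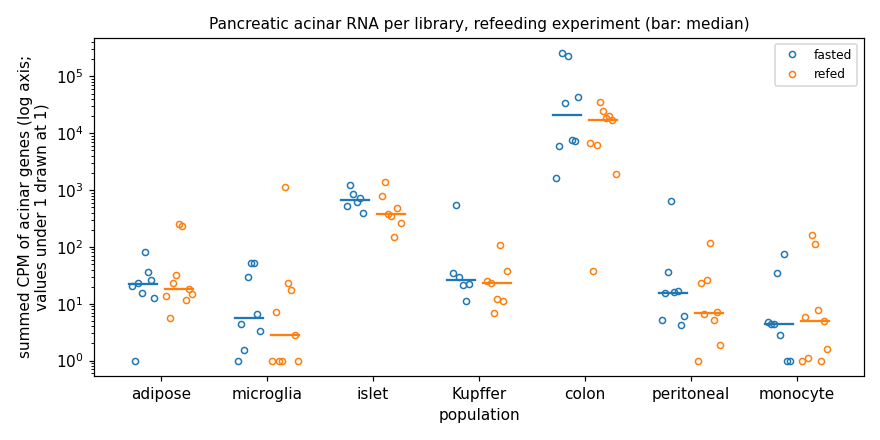
Summed level (CPM, log axis) of pancreatic acinar genes in each library of the refeeding experiment, by population and treatment, with values under 1 drawn at 1 and bars at the median. The median was 16822 CPM over the colonic libraries, 519 CPM over islet macrophages and 4.34 CPM over microglia.

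Blood monocytes of refed mice expressed less of the non-classical monocyte markers as a set (median -0.49, 2 of 15 higher, camera adjusted p 0.00841, adjusted p = 0.751 with an estimated correlation, no call by voom) and less of the MHC class II genes that present antigen (median -0.50, 3 of 13 higher, camera adjusted p 0.0443, adjusted p = 0.751 with an estimated correlation). Itgal, an integrin used for patrolling vessel walls, stood at 579 ± 128 CPM in 8 fasted and 458 ± 155 CPM in 9 refed libraries (-0.37 ± 0.16, adjusted p 1), and Cd74, the invariant chain, at 1909.9 ± 1462 and 1360.0 ± 1145 CPM (-0.58 ± 0.37, adjusted p 1). Erythrocyte genes fell (median -0.41, 0 of 7 higher, camera adjusted p 0.0443, adjusted p = 0.751 with an estimated correlation). Acer3, an alkaline ceramidase gene, had the smallest p, at 342 ± 49.6 CPM fasted and 228 ± 56.5 CPM refed (-0.64 ± 0.11, adjusted p 0.222). Of 10503 genes edgeR called 0, with 278 (2.65%) at an unadjusted p below 0.05. There were 0 by voom with quality weights and 423 by DESeq2.

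**Figure D3:**
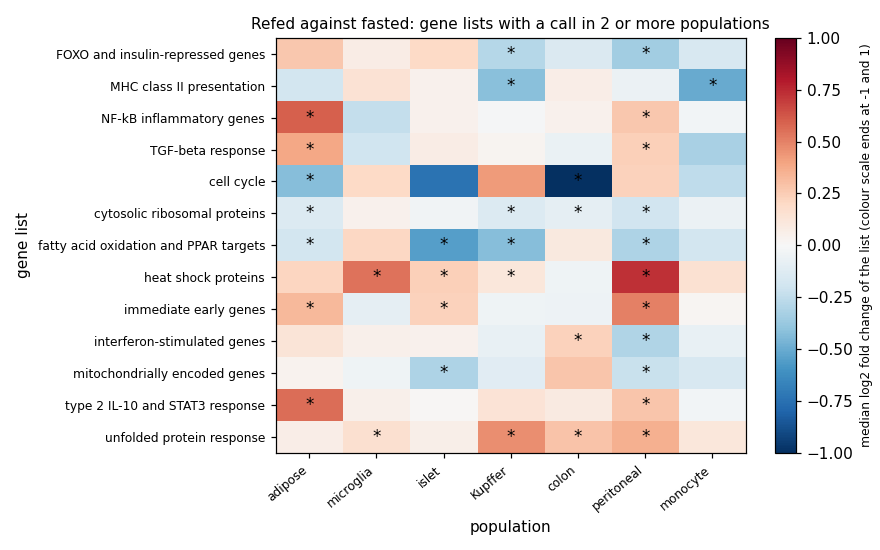
Median log2 change with refeeding of gene lists called in at least 2 populations, by population, with colour ending at -1 and 1 and a star where the camera adjusted p passed at the preset correlation. The unfolded protein response carries a star in microglia, Kupffer cells, colonic macrophages and peritoneal macrophages, with medians from 0.16 to 0.46.

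Across the 7 populations the refeeding effect differed for 5 of 18640 genes in the joint fit, with 1400 at an unadjusted p below 0.05. Other splits of the libraries called up to 10, so chance cannot be excluded for that count. Ptgir, the prostacyclin receptor gene (adjusted p 0.00124), and the sialyltransferase gene St3gal1 (adjusted p 0.0119) were among them. St3gal1 had a log2 change of 5.05 in microglia and -0.77 in monocytes. The opposite directions of Hspa1a, at -1.29 in adipose tissue macrophages, 3.03 in microglia and 2.07 in peritoneal macrophages, did not pass (adjusted p 0.0515). The heat shock list of peritoneal macrophages was raised more than in the other populations (camera adjusted p 6.82e-12, and 0.0171 with an estimated correlation), in a test whose lists were chosen after their results in each population were seen.

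In peritoneal macrophages, high-fat diet with STZ raised markers of adipose tissue macrophages and lowered markers of large peritoneal macrophages. As lists, both were called at the preset correlation only. Gas6, a bridge between dying cells and their receptors (chromosome 8, 13465374 to 13494490, minus strand), rose by 3.16 ± 0.51 log2 units over normal diet, from 5.02 ± 1.65 to 54.01 ± 38.2 CPM (n = 5 each, adjusted p 0.0132), and its exons overlap Tmem255b on the other strand. The mannose receptor gene Mrc1 (chromosome 2, 14229392 to 14332057) rose from 31.6 ± 17.6 to 229 ± 155 CPM (2.62 ± 0.50, adjusted p 0.0285). Tns1, which links integrins to actin (chromosome 1, 73910231 to 74124449), rose from 15.8 ± 4.94 to 98.7 ± 39.002 CPM (2.60 ± 0.26, adjusted p 0.000882). Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), fell from 33.4 ± 15.1 to 3.87 ± 3.56 CPM (-3.29 ± 0.58, adjusted p 0.02), with exons that overlap Gm42793 on the same strand. Cd24a, a surface sialoglycoprotein gene, fell from 437 ± 153 to 84.1 ± 18.3 CPM (-2.33 ± 0.26, adjusted p 0.00116). Gata6, the transcription factor of large peritoneal macrophages, fell from 30.9 ± 3.44 to 12.3 ± 6.10 CPM (-1.42 ± 0.30, adjusted p 0.0419).

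Of 13225 genes edgeR called 171 in that comparison, 88 higher and 83 lower with STZ. The glucocorticoid receptor target genes rose as a set (median 0.36, 18 of 22 higher, 4 called over all genes and 7 adjusted over the list alone, camera adjusted p 1.11e-05, adjusted p = 0.123 with an estimated correlation). Within it the mediator of glucocorticoid action Tsc22d3 went from 224 ± 50.01 to 564 ± 163 CPM (1.32 ± 0.18, adjusted p 0.00339) and the clock gene Per1 from 37.9 ± 22.7 to 137 ± 31.4 CPM (1.97 ± 0.25, adjusted p 0.00237). Cell cycle genes rose (median 0.75, 38 of 40 higher, 0 called over all genes by edgeR and 19 adjusted over the list alone, camera adjusted p 2.92e-14, adjusted p = 0.461 with an estimated correlation). The topoisomerase gene Top2a stood at 82.5 ± 31.8 and 164 ± 43.05 CPM (adjusted p 0.0734). Adipose tissue macrophage markers, to which Gas6 and Mrc1 belong, rose too (median 1.01, 11 of 14 higher, camera adjusted p 6.3e-05, adjusted p = 0.461 with an estimated correlation). Large peritoneal macrophage markers fell (median -0.67, 1 of 18 higher, camera adjusted p 2.68e-08, adjusted p = 0.429 with an estimated correlation). The phosphatidylserine receptor gene Timd4 stood at 381 ± 207 and 143 ± 93.6 CPM (adjusted p 0.0566).

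Genes of cytosolic ribosomal proteins fell in the same comparison (median -0.58, 0 of 61 higher, 51 called adjusted over the list alone, camera adjusted p 3.05e-19, adjusted p = 0.513 with an estimated correlation), and without both libraries of cohort 3 their median was -0.30. LXR target genes rose (median 0.50, 10 of 13 higher, camera adjusted p 0.00318, adjusted p = 0.144 with an estimated correlation), and their median was 0.29 without those libraries. Nr1h3, the gene of LXR alpha itself, stood at 4.25 ± 1.19 and 11.5 ± 2.21 CPM (1.44 ± 0.25, adjusted p 0.0194). Lists of other cells went down. Adipocyte and preadipocyte markers had 656 ± 134 CPM on normal diet and 197 ± 88.5 CPM with STZ (camera adjusted p 0.000484, adjusted p = 0.123 with an estimated correlation). Most of that sum was the preadipocyte gene Pi16 (209 ± 38.2 and 38.8 ± 23.7 CPM, adjusted p 0.00474) and the fatty acid carrier gene Fabp4 (479 ± 164 and 131 ± 70.7 CPM, adjusted p 0.0331). The levels of these genes are scaled by TMM and the list sum is not, so together they can exceed it. Macrophages express Fabp4 too. Without both libraries of cohort 3, 2 of 6 members were higher (median -1.095). B and plasma cell genes fell as well (median -1.64, 1 of 14 higher, camera adjusted p 1.93e-08, adjusted p = 0.429 with an estimated correlation), and so did those of mast cells, basophils and eosinophils (median -1.27, 0 of 8 higher, camera adjusted p 0.00104, adjusted p = 0.429 with an estimated correlation). Genes encoded by mitochondrial DNA fell (median -0.47, 0 of 7 higher, camera adjusted p 0.00641, adjusted p = 0.654 with an estimated correlation), with a median of -0.23 without both libraries of cohort 3. Single libraries weighed on the count, which was 30 without STZ replicate 4 and 301 without STZ replicate 2. Tns1, Cd24a, Per1, Tsc22d3 and Pi16 passed whichever of the 14 libraries was left out, while Gas6 passed in 9, Spp1 in 10, Mrc1 in 8 and Gata6 in 3 of the 14 fits.

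**Figure D4:**
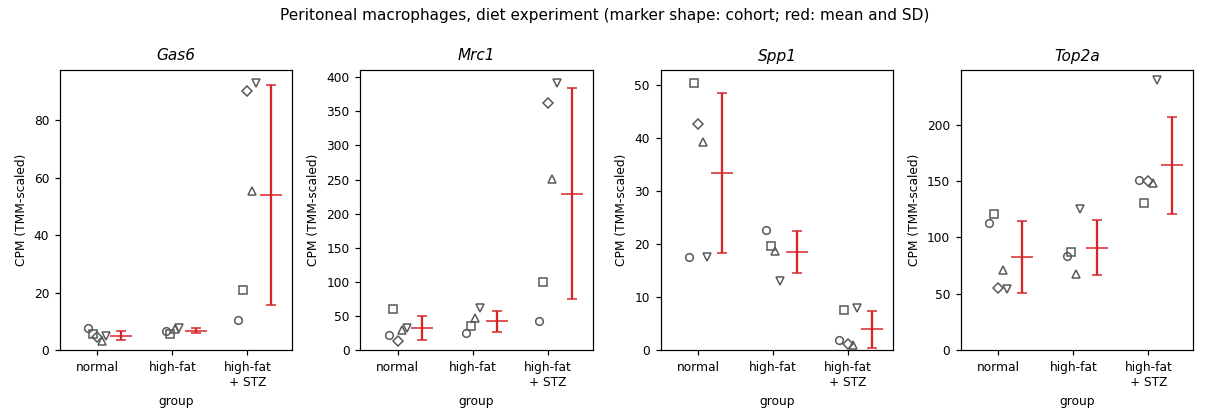
Level (CPM) of Gas6, Mrc1, Spp1 and Top2a in each peritoneal library on normal diet (n = 5), high-fat diet (n = 4) and high-fat diet with STZ (n = 5). Marker shape gives the cohort and red marks the mean with SD. Mrc1 averaged 31.6 CPM on normal diet and 229 CPM with STZ.

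Against high-fat diet alone, STZ raised cell cycle genes of peritoneal macrophages. All 40 cell cycle genes were higher (median 0.85, camera adjusted p 9.01e-23, adjusted p = 0.297 with an estimated correlation), with 17 called adjusted over the list alone. Mki67, a marker of dividing cells, stood at 49.6 ± 15.5 CPM on high-fat diet (n = 4) and 94.7 ± 42.2 CPM with STZ (n = 5, adjusted p 0.349). Glucocorticoid receptor target genes rose (median 0.45, 18 of 22 higher, camera adjusted p 3.73e-07, adjusted p = 0.0583 with an estimated correlation), and so did interferon-stimulated genes (median 0.50, 35 of 39 higher, camera adjusted p 0.000151, adjusted p = 0.713 with an estimated correlation). Large peritoneal macrophage markers fell (median -0.64, 3 of 18 higher, camera adjusted p 2.99e-08, adjusted p = 0.297 with an estimated correlation). Serpinb2, an inhibitor of plasminogen activators, stood at 2356 ± 299 and 1323 ± 530.2 CPM (adjusted p 0.239). Classical monocyte markers rose (median 0.26, 9 of 16 higher, camera adjusted p 0.0179, adjusted p = 0.25 with an estimated correlation), with a median of 0.40 without both libraries of cohort 3. RNA of other cells fell, as adipocyte genes (median -0.99, 2 of 6 higher), B and plasma cell genes (-0.84, 1 of 14) and mast cell genes (-1.17, 0 of 8), with camera adjusted p of 0.00133, 1.53e-05 and 0.000151. With an estimated correlation these were 0.14, 0.498 and 0.297, and the B and plasma cell call was not made by voom or without the replicate block. Genes encoded by mitochondrial DNA fell (median -0.38, 0 of 7 higher, camera adjusted p 0.000685, not passed with an estimated correlation). The smallest adjusted p was 0.0541, held among others by the unnamed genes Gm30978 and Gm16587, the second of which overlaps Selp on the other strand. Of 13225 genes edgeR called 0, with 1069 at an unadjusted p below 0.05. There were 381 by voom with quality weights and 251 by DESeq2, and edgeR called 64 without STZ replicate 2.

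With high-fat diet alone no peritoneal gene passed. Tns1 stood at 15.8 ± 4.94 CPM on normal diet (n = 5) and 40.8 ± 5.29 CPM on high-fat diet (n = 4, 1.46 ± 0.27, adjusted p 0.545). The circadian clock genes rose as a set (median 0.26, 12 of 16 higher, camera adjusted p 0.0126, adjusted p = 0.742 with an estimated correlation). Without both libraries of cohort 3 their median was 0.15 and the call was lost (adjusted p 0.0769). Per1 stood at 37.9 ± 22.7 and 80.5 ± 22.8 CPM (1.14 ± 0.26, adjusted p 0.584). Genes of cytosolic ribosomal proteins fell (median -0.29, 0 of 61 higher, camera adjusted p 1.12e-10, adjusted p = 0.751 with an estimated correlation). Genes of oxidative phosphorylation moved likewise (median -0.22, 3 of 59 higher, camera adjusted p 2.47e-05, adjusted p = 0.823 with an estimated correlation). Without cohort 3 these medians were -0.15 and -0.08 (adjusted p 1.46e-06 and 0.0463), with 12 of 59 oxidative phosphorylation genes higher. B and plasma cell genes fell (median -0.72, 0 of 14 higher, camera adjusted p 0.000923, adjusted p = 0.742 with an estimated correlation), with no call without the replicate block. Neutrophil genes fell (median -0.43, 1 of 6 higher, camera adjusted p 0.0257, adjusted p = 0.742 with an estimated correlation), a call lost without cohort 3 (median -0.21, adjusted p 0.0769), by voom and without the block. Cyp26a1, which degrades retinoic acid, had the smallest p, at 13.9 ± 11.8 CPM on normal and 0.615 ± 0.981 CPM on high-fat diet (-4.65 ± 0.65, adjusted p 0.0947). Of 13225 genes edgeR called 0, with 468 (3.54%) at an unadjusted p below 0.05. There were 8 by voom with quality weights, about 1.1e+02 by DESeq2 and 23 by DESeq2 on genes counted in at least 0.5 of the libraries, and edgeR called 2 without normal-diet replicate 3.

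In islet macrophages, the lists of lysosome and lipid-associated macrophage genes were higher with STZ on high-fat diet, at the preset correlation only. Ctsd, a lysosomal protease gene (chromosome 7, 142375911 to 142388038, minus strand), stood at 536 ± 204 CPM on normal diet (n = 4), 804 ± 350.1 CPM on high-fat diet (n = 4) and 2472 ± 339 CPM with STZ (n = 3). Its log2 change was 2.33 ± 0.27 against normal diet (adjusted p 0.0578) and 1.76 ± 0.25 against high-fat diet (adjusted p 0.574), and Gm49369 overlaps it on the same strand. Plin2, a lipid droplet coat gene, stood at 612 ± 232, 897 ± 351 and 1171 ± 76.5 CPM, and Lgals3bp, a secreted scavenger protein gene, at 469.6 ± 131, 626 ± 216 and 1375 ± 271 CPM, with adjusted p against normal diet of 0.0578 and 0.0604. The lysosome genes rose as a set against normal diet (median 0.43, 34 of 39 higher, camera adjusted p 1.56e-12, adjusted p = 0.391 with an estimated correlation) and against high-fat diet (median 0.38, 34 of 39 higher, camera adjusted p 9.76e-17, adjusted p = 0.292 with an estimated correlation). Lipid-associated macrophage genes rose too (median 0.41, 18 of 24 higher, camera adjusted p 2.26e-08, adjusted p = 0.232 with an estimated correlation against normal diet; median 0.55, 20 of 24 higher, camera adjusted p 7.84e-15, adjusted p = 0.142 with an estimated correlation against high-fat diet). Among their members Igf1, a growth factor gene, stood at 17.8 ± 10.9 CPM on normal diet and 114.4 ± 22.5 CPM with STZ (adjusted p 0.422).

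LXR target genes rose with STZ in islet macrophages against normal diet (median 0.80, 10 of 13 higher, 6 called adjusted over the list alone, camera adjusted p 2.61e-05, adjusted p = 0.208 with an estimated correlation). Apoe stood at 22947 ± 4202 and 33836 ± 2623 CPM (0.63 ± 0.15, adjusted p 0.59). MHC class II genes fell (median -0.26, 2 of 13 higher, camera adjusted p 0.0391, adjusted p = 0.365 with an estimated correlation), with no call without the replicate block. Their regulator Ciita stood at 172 ± 42.8 and 90.99 ± 37.6 CPM (adjusted p 0.843). Genes of cytosolic ribosomal proteins fell (median -0.34, 4 of 62 higher, camera adjusted p 8.04e-07, adjusted p = 0.705 with an estimated correlation). The median over all genes was itself -0.15 against normal diet and -0.29 against high-fat diet, which sets the level against which these lists stand. For 4 lists against high-fat diet the signs differ. Complement and efferocytosis receptor genes, which clear dying cells, rose by the test (median 0.25, mean -0.15, camera adjusted p 0.00105, adjusted p = 0.292 with an estimated correlation), fatty acid oxidation and PPAR target genes likewise (median 0.16, mean -0.32, camera adjusted p 0.0231, adjusted p = 0.292 with an estimated correlation), and the islet macrophage markers rose by the test with a median of -0.07 and a mean of -0.34 (camera adjusted p 0.0416, adjusted p = 0.325 with an estimated correlation). Neutral lipid storage and lipolysis genes rose by the test with a median of -0.15 and a mean of -0.02 (camera adjusted p 0.00835, adjusted p = 0.292 with an estimated correlation). Without STZ replicate 5, of low voom weight, the calls of the islet macrophage markers (median 0.16, adjusted p 0.312) and of neutral lipid storage (median 0.15, adjusted p 0.0526) were lost. The median of fatty acid oxidation was then 0.34 (adjusted p 0.0365). None of these 3 calls was made without the replicate block, nor that of the islet macrophage markers by voom. B and plasma cell genes fell against normal diet (median -4.62, 1 of 10 higher, camera adjusted p 0.0105, adjusted p = 0.605 with an estimated correlation). That call was lost without STZ replicate 5 (median -1.50, adjusted p 0.89) and without the replicate block. Their summed level was 17187.5 CPM in normal-diet replicate 5 and 24516 CPM in high-fat replicate 5. Against high-fat diet the lists of B and plasma cells (median -2.87), neutrophils (-4.00) and pancreatic acinar cells (-3.85) fell, with camera adjusted p of 0.0356, 0.0389 and 0.00483, each 0.678 with an estimated correlation. These calls were lost without the replicate block and without STZ replicate 5, where the medians were -0.06, -2.20 and -2.84 (adjusted p 0.903, 0.242 and 0.238). Of 12406 genes edgeR called 0 against normal diet and 0 against high-fat diet, with 702 and 619 at an unadjusted p below 0.05, 5 and 0 by voom with quality weights and 2039 and 1939 by DESeq2, and edgeR called 1 against normal diet without normal-diet replicate 5.

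With high-fat diet alone, the islet macrophage glucocorticoid receptor gene Nr3c1 stood at 32.6 ± 12.7 CPM on normal and 80.4 ± 18.2 CPM on high-fat diet (n = 4 each, 1.34 ± 0.32, adjusted p 1), and the elastase gene Mmp12 at 2259.5 ± 1022 and 1427 ± 704 CPM (-0.74 ± 0.15, adjusted p 1). Antioxidant NRF2 target genes fell as a set (median -0.23, mean -0.001, 3 of 24 higher, camera adjusted p 0.000271, adjusted p = 0.267 with an estimated correlation). The iron store gene Fth1 stood at 17802 ± 3356 and 14399.7 ± 3946 CPM (adjusted p 1). Genes of cytosolic ribosomal proteins fell (median -0.23, 3 of 62 higher, camera adjusted p 9.8e-12, adjusted p = 0.716 with an estimated correlation), and heat shock genes rose (median 0.38, 17 of 19 higher, camera adjusted p 0.0146, adjusted p = 0.82 with an estimated correlation), the latter with no call without the replicate block. The median over all genes was 0.13. Of 12406 genes edgeR called 0, with 300 (2.42%) at an unadjusted p below 0.05. There were 0 by voom with quality weights, 1906 by DESeq2 and 77 by DESeq2 on genes counted in at least 0.5 of the libraries.

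Microglia expressed more heat shock genes in both high-fat groups. Hspa1a stood at 1084 ± 207 CPM on normal diet, 2134 ± 721 CPM on high-fat diet and 2557 ± 531 CPM with STZ (n = 4 each), with log2 changes of 0.96 ± 0.20 and 1.31 ± 0.21 against normal diet (adjusted p 1 and 0.874). STZ replicate 9 is the only library of its cohort, so with the cohort term all log2 changes with STZ in microglia rest on 3 STZ libraries. The co-chaperone gene Bag3 stood at 164 ± 49.9 CPM on high-fat diet and 228 ± 61.3 CPM with STZ (0.75 ± 0.24, adjusted p 1). The list rose against normal diet on high-fat diet (median 0.41, 17 of 20 higher, camera adjusted p 2.64e-07, adjusted p = 0.481 with an estimated correlation) and with STZ (median 0.49, 18 of 20 higher, 11 called adjusted over the list alone, camera adjusted p 2.87e-22, adjusted p = 0.211 with an estimated correlation). It also rose with STZ against high-fat diet (median 0.32, 16 of 20 higher, camera adjusted p 0.00639, adjusted p = 0.99 with an estimated correlation). Neutrophil RNA moved with it against normal diet, where the list rose on high-fat diet (median 1.53, 10 of 11 higher, camera adjusted p 0.000765, adjusted p = 0.481 with an estimated correlation) and with STZ (median 1.16, 10 of 11 higher, camera adjusted p 0.000344, adjusted p = 0.529 with an estimated correlation). Without high-fat replicate 2 and normal-diet replicate 17, of low voom weight, these medians were 3.46 and 3.99. Its summed level was 823 ± 155, 1514 ± 925 and 813 ± 175 CPM in the 3 groups, so with STZ the sum did not follow the median.

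Glucocorticoid receptor target genes rose in microglia on high-fat diet (median 0.25, 19 of 20 higher, camera adjusted p 0.0391, adjusted p = 0.405 with an estimated correlation) and with STZ (median 0.19, 16 of 20 higher, camera adjusted p 0.0392, adjusted p = 0.529 with an estimated correlation, no call by voom). Per1 stood at 339 ± 49.9 CPM on normal and 492 ± 101.4 CPM on high-fat diet (0.54 ± 0.17, adjusted p 1). Cebpd, an inflammatory transcription factor gene in the same list, pointed the other way on high-fat diet (63.0 ± 29.5 and 16.8 ± 5.88 CPM, -1.85 ± 0.39, adjusted p 1) and stood at 84.9 ± 52.1 CPM with STZ (2.66 ± 0.41 against high-fat diet, adjusted p 0.255). The exons of Spidr overlap it on the other strand. The complement gene C1qc, which tags material for uptake, stood at 4292 ± 757 CPM on normal and 1927 ± 1629 CPM on high-fat diet (adjusted p 1). Of 13972 genes edgeR called 0 in each of the 3 comparisons (high-fat against normal, STZ against normal, STZ against high-fat). An unadjusted p below 0.05 was held by 441, 300 and 666 (3.16, 2.15 and 4.77%). Voom with quality weights called 0, 0 and 0 and DESeq2 130, 198 and 277 in these comparisons. Without high-fat replicate 16 edgeR called 1 gene in the first and 1 in the last of them.

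Diet and STZ effects were compared among the 3 populations in joint fits. The high-fat diet effect differed for 53 of 17230 genes, with 1341 at an unadjusted p below 0.05, and that of STZ over high-fat diet for 122, with 1920 at an unadjusted p below 0.05. Nr3c1 had a log2 change with high-fat diet of 1.38 in islet macrophages, -0.17 in peritoneal macrophages and -0.04 in microglia (adjusted p 0.00711). Ctsd had a log2 change with STZ of 1.72 in islet macrophages, 0.00 in peritoneal macrophages and -0.09 in microglia (adjusted p 0.00251). The lipid receptor gene Lpar5 (adjusted p 0.000181) led the high-fat diet fit. The ubiquitin ligase gene Trim39 (adjusted p 0.000286) led that of STZ, with 0 counts in the STZ islet libraries. Splits of the libraries by other labels called up to 792 and 142 genes, so chance cannot be excluded for either count. Islet libraries started from 400 cells, peritoneal libraries from 100000 and microglia from 5000, so the populations also differ in sampling noise. The joint fits used a single spread per gene for all of them. In the separate fits the common coefficient of variation was 1.18 in islet macrophages, 0.3 in peritoneal macrophages and 0.87 in microglia. A change in the noisier islet libraries can therefore pass more easily in the joint fits. In the islet fits alone edgeR called neither Nr3c1 with high-fat diet nor Ctsd with STZ against high-fat diet (adjusted p 0.574 for Ctsd).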

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

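Chosen only after the result was seen were the tests of RNA quality, of single other-cell lists, of monocyte-derived or dendritic cells, of B and mast cells, of spill from islet libraries and of refeeding on the pancreatic share, the lists compared between populations, and the sets of other-cell levels searched for a library that stands apart.

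Heat shock genes rose with refeeding in peritoneal macrophages, and their list was raised there more than in the other populations (camera adjusted p 0.0171 with an estimated correlation). A score of the list was 0.92 log2 units higher in 8 refed than in 8 fasted libraries (exact p 0.00185 over 1080 within-cohort permutations). With a covariate the permutations moved the treatment but left the covariate in place. Those permutation p are therefore not exact and can be too small, so the share of the effect kept is weighed below. Stress of cell handling, read from immediate early genes, is argued against as the whole cause. With their score as a covariate 0.782 of the effect was kept (permutation p 0.000926). That score was itself 0.41 log2 units higher in refed libraries (exact p 0.087). The summed share of other cells decides nothing, though 1.05 of the effect was kept with it as a covariate (permutation p 0.00278). The reason is that dendritic cell genes, the only other-cell list called there, hold 0.0123 of that sum. RNA of dendritic cells, endothelial cells or hepatocytes, as read by their lists, is argued against as the whole cause. Their levels rose by 0.55, 0.36 and 0.20 log2 units (exact p 0.00185, 0.00556 and 0.0481). With each as the covariate 1.32, 1.16 and 0.929 of the effect was kept. No other list level moved at an exact p below 0.05, so for those a kept share near 1 says little. With each of 18 lists in turn as the covariate at least 0.897 was kept (largest permutation p 0.0037). RNA quality was not measured, and the mitochondrial share of counts stands in for it. That share fell with refeeding (-0.34 log2 units, exact p 0.00185). With it as a covariate 0.960 of the effect was kept (permutation p 0.000926). This argues against the share as the whole cause. Whether the share follows RNA quality is unknown, so RNA quality itself stays open. A response to feeding may underlie the rise, as a hypothesis found and tested on the same data.

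With high-fat diet and STZ, cell cycle genes of peritoneal macrophages rose and large peritoneal macrophage markers fell against normal diet. Both list calls were made at the preset correlation only, and edgeR called 0 cell cycle genes over all genes. The 2 libraries of cohort 3 are argued against as the cause of the cell cycle rise, since its median was 0.87 without them (0.75 with them), with 40 of 40 genes higher. B and mast cells entering the sort are argued against for the fall of the markers, since the higher of their list medians was -1.27. Monocyte-derived or dendritic cells remain possible, since 0 of 3 list medians lay below 0 by more than their standard error (monocyte 0.16 ± 0.30, MHC class II -0.15 ± 0.25, dendritic -0.16 ± 0.22) and members went both ways. A change of state in resident cells and the entry of such cells cannot be told apart here.

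Pancreatic enzyme RNA was abundant in colonic libraries. Spill from islet libraries is argued against, since the colonic median of 16822 CPM was 55.5 times the median of 303 CPM over islet libraries of both experiments. In the refeeding experiment alone, which holds all colonic libraries, the islet median was 519 CPM. RNA of acinar cells reaching the sorted cells may be the source, since the acinar genes moved together across 17 libraries, with a median slope of 0.77 on Prss2. Whether refeeding lowers that share stays open (-1.79 log2 units, exact p 0.143 over 2160 permutations).

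The other libraries of a group lay apart from 1 library in 12 of 67 sets searched. About 1 in 20 sets would hold such a library by chance, but since part of the sets was picked by eye the number cannot be read against it. Total counts were 19.04 M in normal-diet peritoneal replicate 4 (others 14.4 to 15.2). Cirbp was at 200.2 CPM in refed microglia replicate 6 (others 23.5 to 81.5), and the same library held B and plasma cell RNA at 9374 CPM (others 515 to 1019.5). Stxbp3 was at 156 CPM in refed peritoneal replicate 6 (others 48.4 to 98.6). Cyp26a1 was at 34.5 CPM in normal-diet peritoneal replicate 3 (others 5.21 to 12.0) and at 2.08 CPM in high-fat replicate 5 (others up to 0.247). Mesothelium and fibroblast RNA was at 523 CPM in fasted adipose replicate 5 (others 2.02 to 214) and 1059 CPM in refed replicate 2 (others 82.4 to 485). B and plasma cell RNA was at 17187.5 CPM in normal-diet islet replicate 5 (others 243 to 300.5), 24516 CPM in high-fat islet replicate 5 (others 323 to 332), 907 CPM in normal-diet peritoneal replicate 2 (others 35.8 to 116.2) and 584 CPM in STZ peritoneal replicate 2 (others 8.67 to 65.8).

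Chance cannot be excluded for the number of genes in the 3 joint fits that follow, as the splits below show. Refeeding effects differed by adjusted p among the 7 populations for Ptgir (adjusted p 0.00124), Ifi213 (0.00243), Samd9l (0.00903) and St3gal1 (0.0119), by edgeR and Benjamini-Hochberg. In the same way high-fat diet effects among 3 populations gave Lpar5 (adjusted p 0.000181), Trim2 (0.00548), Steap3 (0.00662), Nr3c1 and Xdh (0.00711 each), Cfap74 (0.00787), Adgrg1 and Exog (0.016 each). The islet log2 change was 9.53 for Trim2, 9.14 for Lpar5, 8.82 for Cfap74, 8.12 for Adgrg1 and 5.82 for Steap3. For Exog it was 5.17 and for Nr3c1 1.38. In microglia Xdh changed by 10.1 and Steap3 by -9.51. STZ effects gave Trim39 and Lhfpl2 (adjusted p 0.000286 each), Accs and Exog (0.000556 each), Adamts1 (0.000628), Cass4 (0.000838), Prkdc (0.00218) and Ctsd (0.00251). The islet log2 change with STZ was -12.5 for Trim39, -11.4 for Accs, -10.9 for Cass4 and -9.76 for Exog. It was -9.20 for Adamts1, -7.62 for Prkdc and 1.72 for Ctsd, while Lhfpl2 changed by 6.18 in peritoneal macrophages. Genes detected per islet library ran from 9864 to 12441 with STZ, 12036 to 14536 on high-fat diet and 10828 to 13314 on normal diet. Whether the largest changes reflect missed detection in libraries of 400 cells was not tested. Of 35 list differences with refeeding 21 passed at the preset correlation and 1 with an estimated correlation, against 9 and 0 of 33 with diet and 18 and 0 of 51 with STZ by camera.

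Called genes were also counted after other splits of the libraries. Chance can be excluded for the 670 population-specific genes (highest other 1, 1 of 25 splits as large). For the 49 genes of peritoneal refeeding 1 of 100 splits was as large, the real one, a share below 0.05. However, a further split called 48, so chance is not excluded there. The replicate number as the block left 0 genes, but same-numbered libraries there share no animal (mean correlation 0.027). That block also leaves fewer degrees of freedom, so its count says little about chance. The refeeding splits did not keep the cohorts. Where edgeR called 0 genes every split is as large, so the splits say nothing about chance there. With refeeding this was 100 of 100 splits, and the highest other was 1 in adipose tissue macrophages, 2 in microglia, 3 in islet macrophages, 1 in Kupffer cells, 6 in colonic macrophages and 3 in monocytes. In microglia of the diet experiment it was 35 of 35 splits (highest other 31 for high-fat diet, 1 for STZ and 4 for STZ against high-fat diet). Chance cannot be excluded for the genes that differ among populations with refeeding (5, highest other 10, 10 of 22 splits), high-fat diet (53, highest other 792, 15 of 40) and STZ (122, highest other 142, 4 of 40). The 792, many times the real count, point to a structure of the samples whose cause was not tested. Splits that part as many same-cohort pairs were too few for a share below 0.05 in islet macrophages (0 genes and highest other 0 in each of 3 comparisons, 8 of 8 splits) and in peritoneal macrophages with high-fat diet (0, highest other 0, 16 of 16), STZ against normal diet (171, highest other 0, 1 of 16) and STZ against high-fat diet (0, highest other 1, 16 of 16). Splits that part fewer pairs called up to 170 genes in STZ against normal diet, 1 in high-fat against normal diet and about 1.1e+02 in STZ against high-fat diet of peritoneal macrophages, and 207 in high-fat against normal diet of islet macrophages, which points to a structure of those samples whose cause was not tested.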

How the results depend on the processing

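Chosen only after the result was seen were leaving out libraries with a low voom weight, DESeq2 on genes counted in at least 0.5 of the libraries, and leaving out 4 colonic or 2 microglia libraries. Counts are given as refeeding in adipose tissue macrophages, then microglia, then islet macrophages, then Kupffer cells, then colonic macrophages, then peritoneal macrophages and last monocytes, where edgeR called 0, 0, 0, 0, 0, 49 and 0, and then as high-fat diet against normal, STZ against normal and STZ against high-fat diet in islet macrophages (0, 0, 0), peritoneal macrophages (0, 171, 0) and microglia (0, 0, 0). Unadjusted p below 0.05 were held by 564, 270, 243, 380, 307, 1245 and 278 genes, then 300, 702 and 619, 468, 2597 and 1069, 441, 300 and 666. As percent of the tested genes these were 5.16, 2.59, 2.42, 3.27, 2.59, 10.99 and 2.65, then 2.42, 5.66 and 4.99, 3.54, 19.64 and 8.08, 3.16, 2.15 and 4.77. Without the low-count filter edgeR called 96, 13, 8, 37, 143, 312 and 6, then 0, 4 and 0, 22, 710 and 166, 30, 10 and 48. DESeq2 called 738, 1491, 513, 369, 400, 598 and 423, then 1906, 2039 and 1939, about 1.1e+02, 922 and 251, 130, 198 and 277. On genes counted in at least 0.5 of the libraries it called 124, 60, 57, 75, 46, 391 and 14, then 77, 374 and 211, 23, 930 and 203, 20, 11 and 42. Voom with quality weights called 5, 0, 0, 16, 5, 191 and 0, then 0, 5 and 0, 8, 876 and 381, 0, 0 and 0. RLE size factors moved STZ against normal diet in islet macrophages to 3 and STZ against high-fat diet in peritoneal macrophages to 8. The replicate number as a block moved peritoneal refeeding from 49 to 0, and the mean correlation of same-numbered libraries there was 0.027. Without the block STZ against high-fat diet in peritoneal macrophages had 34. Without low-weight libraries high-fat against normal diet in peritoneal macrophages had 2 and STZ against high-fat diet 21. Leaving out 1 library of the diet experiment gave 30 (without STZ replicate 4) to 301 (without STZ replicate 2) genes for STZ against normal diet and 0 to 64 (without STZ replicate 2) for STZ against high-fat diet in peritoneal macrophages, 0 to 2 (without normal-diet replicate 3) for their high-fat diet, 0 to 1 (without normal-diet replicate 5) for STZ against normal diet in islet macrophages, 0 to 1 (without high-fat replicate 16) for high-fat diet and for STZ against high-fat diet in microglia, and 0 to 0 elsewhere. Of 134 list calls 1 was kept with an estimated correlation, and of the 24 other-cell calls 0 by camera, with 22 called by voom. With the blocks exchanged 15 other-cell calls were made. The B and plasma cell list of STZ against high-fat diet in islet macrophages reversed without low-weight libraries, from a median of -2.87 (adjusted p 0.0356) to -0.06 with an upward test (adjusted p 0.903). Genes that differ among populations with refeeding moved from 5 to 726 without the filter and 146 by voom with the animal as a block, with diet from 53 to 97 and 33 by voom, and with STZ from 122 to 240 and 199. Population-specific genes moved from 670 to 1621 by voom. For named genes, 1156 of 1271 results with 1 library left out were the same, 89 weaker and 26 stronger, and 0 reversed. The cause of these moves was not tested.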

Other observations

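All tests over animals given here were chosen only after the result was seen, since Cirbp was noticed as the gene with the smallest p in microglia. Libraries with the same number and cohort in different populations were taken as those of 1 mouse, which the labels do not state, and the 4 islet libraries that carry the numbers of 2 mice were left out. If libraries of a number came from different mice, the exact p given here are not over animals. Cold-inducible RNA-binding protein genes were lower after refeeding in every population. Scored per animal over its libraries (9 refed and 8 fasted mice), Cirbp and Rbm3 fell by 0.81 log2 units (exact p 0.000926, adjusted p 0.00463 over 5 tests, smallest possible 0.000463). The fold change was negative in 7 of 7 populations for each gene, from -1.83 to -0.18 for Cirbp and from -0.91 to -0.17 for Rbm3, though in no population did either pass the adjusted p of edgeR. Leaving out any population kept the exact p between 0.000463 and 0.000926. Both proteins rise at low body temperature, so a warmer body after a meal may explain the 0.81, but body temperature is not given in the labels, the clock and feeding itself were not tested, and no test here decides it. Heat shock genes, which heat raises, did not follow in every population. Their list was lower than in the other populations in adipose tissue macrophages (camera adjusted p 0.00166), colonic macrophages (5.88e-06) and monocytes (0.0115), with 0.25, 0.158 and 0.381 by an estimated correlation, and Hspa1a changed by -1.29 in adipose tissue macrophages.

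The same score per animal rose by 0.27 for heat shock genes (exact p 0.0241, adjusted p 0.0301) and by 0.21 for the unfolded protein response (exact p 0.0102, adjusted p 0.0255), and fell by 0.29 for fatty acid oxidation and PPAR targets (exact p 0.0167, adjusted p 0.0278). Cytosolic ribosomal protein genes fell by 0.09, which did not pass (exact p 0.0727). Single populations weigh on 3 of these. Leaving out a population moved the exact p of ribosomal protein genes between 0.00231 and 0.261, the latter without peritoneal macrophages. Without peritoneal macrophages the exact p was 0.167 for heat shock genes, and without Kupffer cells it was 0.0662 for fatty acid oxidation. For the unfolded protein response leaving out any population kept the exact p at or below 0.0255. A response common to several populations of a mouse may underlie it, though not one of the same size in each, if the preset correlation of camera holds. Its list was called in 4 of 7 populations. It was higher than in the others in Kupffer cells (camera adjusted p 3.57e-05) and peritoneal macrophages (4.81e-05) and lower in adipose tissue macrophages (0.000942), islet macrophages (0.00244) and monocytes (0.00862), with none below 0.166 by an estimated correlation.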
